A study of Mus musculus with 12 samples.

How the data were processed

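Whole-liver total RNA from 12 male mice, extracted with Trizol and turned into Illumina libraries by a service provider, was sequenced in 4 groups of 3 mice, per the labels' protocols. The authors deposited a table of raw read counts per gene for 54532 Ensembl gene identifiers, with 1 column of counts per mouse. Per the submitters' processing notes, the tools were STAR, featureCounts 1.5.0-p3 and the mouse genome build mm10. The STAR version, the strand setting of the counting and the annotation release were not given in the sources used here. In a comparison with GENCODE release M21, which is on the same build, 54495 of the deposited identifiers were found and 98.33% of these had the same chromosome, start and end. All coordinates are those of mm10 as the deposited table gives them. Because strand use is not stated, reads from genes that overlap on opposite strands cannot be told apart. This limits, among the genes named in the text, Abcg5, Abcg8, Acot3, Acot4, Alas2, Cidea, Cyp51, E2f8, Glul, Plin4, Psmb9, Slc25a10, Slc25a23, Srebf1 and Tnnc1. Genes of near-identical families are also uncertain, since counting can divide their reads arbitrarily: the Serpina1, Mup, Cyp2a, Cyp2b, Cyp4a, Acot, C4a and C4b, Cyp21a1 and H2-Q families.

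Groups were taken from the genotype and diet in the labels, and each column was matched to its mouse by name. No deposited row lacked a gene identifier, and 0 columns of sample values were left unused. Total counts per library ranged from 12842187 to 24332663. Libraries of one group were compared with a chi-square test of their counts: none held identical values, and the chi-square per degree of freedom lay between 9.62 and 42.1, far above sampling noise, so each library was kept as its own replicate.

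Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes with enough reads were kept by filterByExpr, which left 14277 genes, library sizes were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood model with 1 mean per group was fitted to all 12 libraries together, so that the groups share an estimate of the spread. The 4 contrasts were knockout against control in each diet and fast-food diet against chow in each genotype, with the difference of the differences as the interaction. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each contrast, with 0.05 as the threshold. Standard errors (SE) of log2 fold changes come from the same fit. Fold changes also come from the fit and can differ from the ratio of the mean levels. Levels are edgeR's CPM, which scale each library's counts by its TMM-adjusted size, given as mean ± SD over the 3 mice of a group. Log2 CPM for principal components and list scores used a prior count of 2. A list score is the mean over the list's genes of log2 CPM centred per gene on the mean of all libraries.

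In all, 47 gene lists on lipid, energy, bile acid and drug metabolism, mitochondria, stress, inflammation, liver cell types and zones, sex bias, the clock, ribosomes and tissues that can be dissected along with liver were fixed from general knowledge of liver biology. Of their 975 symbols 972 were found in the deposited table, and the 44 lists with at least 4 tested genes were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The same lists were tested with camera at an estimated correlation and with fry. Members of each list were also counted with p-values adjusted over the list alone. The lists, the tests, the groups and the rule for the genes named here were chosen before the data were examined. That rule takes Slc25a34 and 10 further genes in every comparison, the 8 largest increases and the 8 largest decreases among protein-coding genes past the threshold with a mean of at least 1 CPM in the higher group and no overlap between the groups' libraries, and up to 4 genes of each list, chosen by the smallest p. Where fewer than 10 genes passed, all were named, and for the interaction the 3 with the smallest p.

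The fit was tested on simulated counts with 200 genes changed by known folds. Counts were drawn independently per gene and library at the fitted spread, with no outlying library. The shares recovered need not hold for the real libraries. For knockout against control on chow, over 14040 genes, it recovered 38.8% of the genes changed 1.5-fold, 71.6% of those changed 2-fold and 98.5% of those changed 4-fold. On fast-food diet, over 14050 genes, the shares were 25.4%, 71.6% and 100%. For the diet effect in control mice, over 14049 genes, they were 34.3%, 65.7% and 98.5%, and in knockout mice, over 14050 genes, 28.4%, 70.1% and 100%. Of 14057 genes simulated without a change, some of which the filter removed before the test, 8, 8, 6 and 5 were called in the 4 comparisons, in the same order.

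The alternatives were size factors by relative log expression, no filter on low counts, a stricter filter of 1 CPM in at least 3 libraries, a robust dispersion, only the 2 groups compared, a block for the mouse number, DESeq2 1.42.0 and leaving out each library in turn. Leaving out together the 2 libraries with raised acute phase genes was added after seeing the data. Figures were drawn with matplotlib 3.10.9.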

Results

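The data describe the livers of 12 male mice that carry loxP sites around the first part of Slc25a34, a gene of the solute carrier family that transports metabolites across the inner mitochondrial membrane. At 2 months of age the mice received an adeno-associated virus that is active in hepatocytes and brings either Cre recombinase, giving a hepatocyte knockout (HKO), or green fluorescent protein, giving the control (WT). According to the labels the virus reaches more than 95% of hepatocytes. After 1 month on chow they were kept for 2 months on chow or on a fast-food diet (FFD), whose composition the sources used here do not give, and were fasted for 16 h before the liver was taken. Each of the 4 groups held 3 mice, and each library counted between 12842187 and 24332663 reads in genes.

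Diet separated the libraries before genotype did. The first principal component carried 33.8% of the variance, with the chow libraries between −32.3 and −18 and the FFD libraries between 16.2 and 30.8. On the second component, with 12.4%, HKO chow replicates 1 and 3 lay at −35.4 and −25.7. HKO chow replicate 2 lay at 17, among the WT chow libraries at 22.8, 20.6 and 8.81. Spearman correlations within groups were 0.982 to 0.992 and those between diets 0.97 to 0.982. In WT chow replicate 3 and WT FFD replicate 2, Saa1, an acute phase protein gene, stood at 1691 and 949.6 CPM against 25.09 to 182.3 CPM in the other libraries, and the acute phase list scored 1.23 and 1.24. HKO chow replicate 2 scored 1.67 for gallbladder and gut genes, where Muc6, a mucin, reached 10.24 CPM, 0.704 for stellate cell genes and 0.735 for immediate early genes.

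The targeted gene was low in every HKO library. Slc25a34 (ENSMUSG00000040740; mm10 chromosome 4, 141618824 to 141623821, minus strand, 5 exons) had 88 to 116 counts in the WT libraries on chow and 4 to 13 in the HKO libraries. Its mean level on chow was 6.27 ± 1.17 CPM in WT and 0.538 ± 0.21 CPM in HKO mice (SD, n = 3 each), 11.2-fold lower by the edgeR fit. On FFD it was 3.32 ± 1.54 CPM in WT and 0.413 ± 0.277 CPM in HKO mice, 7.38-fold lower by the edgeR fit, with 30 to 92 against 4 to 18 counts. The fall on chow passed edgeR's quasi-likelihood test (log2 fold change −3.48, SE 0.45, Benjamini-Hochberg adjusted p = 0.024), and the FFD difference did not (−2.88, SE 0.46, adjusted p = 0.071). An exact two-sided permutation test of log2 CPM gave p = 0.1 in each diet, the smallest value that 3 against 3 mice allow. The loxP sites lie in the promoter and intron 1, so reads from the later exons can remain, and whole liver also holds cells the virus does not reach.

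**Figure D1:**
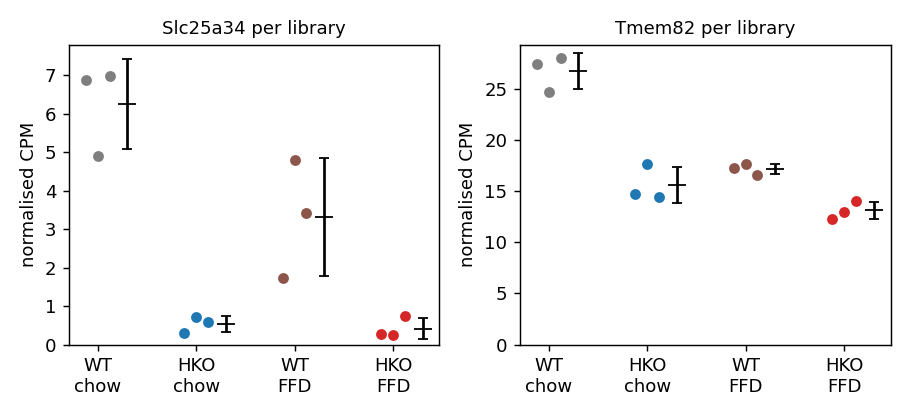
Normalised CPM of Slc25a34 (left) and its neighbour Tmem82 (right) in each of the 12 libraries, by group; points are libraries and the bars mean ± SD of 3. Slc25a34 averaged 6.27 and 3.32 CPM in WT and 0.538 and 0.413 CPM in HKO mice on chow and FFD, with no overlap between genotypes in either diet.

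The first comparison asks what loss of the carrier in hepatocytes changed on chow. Besides Slc25a34, Tmem82 and Odf3b fell in HKO livers. Tmem82, a transmembrane protein gene whose end nearest to Slc25a34 lies 190 bp downstream of it on the same strand (chromosome 4, 141613376 to 141618633), fell from 26.7 ± 1.78 to 15.6 ± 1.79 CPM, with a log2 fold change of −0.77 (SE 0.10). Odf3b (chromosome 15, 89377449 to 89379282) fell from 11.8 ± 1.49 to 6.52 ± 0.112 CPM, with a log2 fold change of −0.85 (SE 0.11). Both had an adjusted p of 0.024 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as did Slc25a34, and 0 genes rose. At an unadjusted p under 0.05 there were 1680 genes where chance gives 714 on average, and DESeq2 called 119. Genes vary together, so counts far from that average can arise by chance, and other splits were not counted at this threshold.

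No member of a gene list passed over all genes on chow, while 13 of 44 lists shifted by camera. Targets of the fatty acid sensor PPARalpha had negative values in 22 of 23 genes (median log2 fold change −0.25, 0 lower adjusted over the list alone, camera adjusted p = 1e-06; adjusted p = 0.35 with an estimated correlation), among them Acot1 at −0.61 (SE 0.18). Their score was 0.0926 in HKO chow replicate 2, inside the WT range of 0.0819 to 0.359, and −0.377 and −0.269 in the other HKO chow libraries. Mitochondrial fatty acid oxidation had negative values in 18 of 20 (median −0.15, 4 lower adjusted over the list alone, camera adjusted p = 9.7e-05; adjusted p = 0.49 with an estimated correlation), with the acyl-CoA dehydrogenase Acadm at −0.37 (SE 0.09). The 6 ketogenesis genes were all negative, with a median of −0.18, and 3 were lower adjusted over the list alone (camera adjusted p = 0.002; adjusted p = 0.38 with an estimated correlation). Among them Acat1 had −0.42 (SE 0.11) and the lactate and ketone transporter Slc16a1 −0.61 (SE 0.15). Lipid droplet genes had a median of −0.17 over 24 genes, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0053; adjusted p = 0.56 with an estimated correlation). Within that list Lpl, a lipase, stood at 1.14 (SE 0.27).

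Genes of hepatocytes around the central vein and of drug metabolism leaned the other way on chow. Of 25 drug metabolism genes 22 were positive, with a median of 0.17 and 3 higher adjusted over the list alone (camera adjusted p = 7.6e-06; adjusted p = 0.35 with an estimated correlation). Their score was −0.2 in HKO chow replicate 2, inside the WT range of −0.478 to −0.171, and 0.229 and 0.155 in the other HKO chow libraries. The cytochrome P450 gene Cyp2a5 averaged 212 ± 92.6 CPM in WT and 694 ± 170 CPM in HKO mice. The pericentral list had a median of 0.15 over 18 genes, with 2 higher adjusted over the list alone (camera adjusted p = 0.0063; adjusted p = 0.35 with an estimated correlation). Its carrier Slc13a3 and the glutamine synthetase Glul stood at log2 fold changes of 1.17 (SE 0.20) and 0.66 (SE 0.12). The 19 clock genes had a median of 0.33 and 4 higher adjusted over the list alone (camera adjusted p = 0.00048; adjusted p = 0.32 with an estimated correlation), with Per2 at 0.75 (SE 0.20). The 14 gluconeogenesis genes had a median of 0.31, with 1 higher adjusted over the list alone (camera adjusted p = 0.038; adjusted p = 0.56 with an estimated correlation), and Igfbp1, an insulin-regulated binding protein, stood at 1.39 (SE 0.33).

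The remaining 5 lists that shifted on chow had 0 members past the threshold adjusted over the list alone. Endoplasmic reticulum (ER) stress genes were positive in 20 of 20, with a median of 0.28 (camera adjusted p = 7.6e-06; adjusted p = 0.68 with an estimated correlation). Their score was 0.696 in WT chow replicate 3, which also had raised acute phase genes, and −0.356 and 0.0733 in the other WT chow libraries. Medians were 0.20 over 22 male-biased liver genes (camera adjusted p = 0.0025; adjusted p = 0.68 with an estimated correlation) and 0.10 over 35 ribosomal protein genes (camera adjusted p = 0.0014; adjusted p = 0.83 with an estimated correlation). The 15 heat shock genes had a median of −0.16 (camera adjusted p = 0.027; adjusted p = 0.83 with an estimated correlation). The 19 immediate early genes had a median of 0.40 (camera adjusted p = 0.027; adjusted p = 0.68 with an estimated correlation), with scores of 0.735 in HKO chow replicate 2 and −0.0647 and −0.128 in the other HKO chow libraries.

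Of the genes fixed in advance, log2 fold changes on chow were 0.28 (SE 0.24) for the mitochondrial coactivator Ppargc1a, −0.12 (SE 0.07) for Tfam, a mitochondrial transcription factor, 0.42 (SE 0.12) for the fatty acid synthase Fasn and −0.64 (SE 0.26) for the desaturase Scd1. They were −0.38 (SE 0.12) for the carnitine transferase Cpt1a, 0.50 (SE 0.60) for the bile acid enzyme Cyp7a1, −1.90 (SE 0.70) for the hormone Fgf21, 0.68 (SE 0.60) for the collagen Col1a1, 0.28 (SE 0.56) for the macrophage receptor Trem2 and −0.16 (SE 0.12) for albumin, Alb. None passed edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p between 0.22 and 0.89. All 3 calls on chow ended when WT replicate 1, HKO replicate 1 or HKO replicate 3 was left out (Benjamini-Hochberg adjusted p = 0.11, 0.21 and 0.23 by edgeR's quasi-likelihood test, the range over all alternatives being 1.5e-09 to 0.23 for Slc25a34, 2.8e-06 to 0.23 for Tmem82 and 3.2e-05 to 0.23 for Odf3b). With only the 2 groups compared, Tmem82 and Odf3b also failed (adjusted p = 0.21 for both by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and Slc25a34 passed (0.039). Without HKO replicate 2 there were 313 calls, without WT replicate 3 there were 12, and 14 without the 2 libraries with raised acute phase genes. The camera calls of the lipid droplet, ketogenesis, gluconeogenesis, pericentral, male-biased, immediate early, heat shock and ribosomal lists on chow ended with some library left out, the heat shock median being 2.97e-05 without WT chow replicate 3. The list calls are weak evidence for a genotype effect, since the other 9 splits of these 6 libraries called 8 to 20 lists, 5 of them at least as many as the 13.

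The second comparison asks the same on FFD, where a single gene passed. Serpina1e, of the alpha-1-antitrypsin family of secreted protease inhibitors (chromosome 12, 103946931 to 103958975), fell in HKO mice from 2401 ± 301 to 728 ± 243 CPM, 3.3-fold, with a log2 fold change of −1.72 (SE 0.20, adjusted p = 0.015 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It has near-identical paralogs, so its level is uncertain. At an unadjusted p under 0.05 there were 1333 genes where chance gives 714 on average, with the same limit as on chow, and DESeq2 called 130. Tmem82 had a log2 fold change of −0.39 (SE 0.10).

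Interferon-induced genes and lymphocyte markers had lower values in HKO than in WT livers on FFD. All 29 interferon response genes were negative, with a median of −0.59 and 16 lower adjusted over the list alone (camera adjusted p = 4.2e-25; adjusted p = 0.14 with an estimated correlation). The immunoproteasome subunit Psmb9 averaged 25.2 ± 4.93 CPM in WT and 13.1 ± 0.389 CPM in HKO mice, and the antiviral Ifit1 15.4 ± 2.3 and 7.03 ± 1.83 CPM. All 20 lymphocyte and dendritic cell markers were negative, with a median of −0.79 and 5 lower adjusted over the list alone (camera adjusted p = 9.4e-11; adjusted p = 0.24 with an estimated correlation). Their scores were 0.588, 0.165 and 1.09 in WT FFD replicates 1 to 3 and 0.196, −0.412 and −0.501 in HKO FFD replicates 1 to 3, and the median was −0.51 without WT FFD replicate 3 and −1.26 without HKO FFD replicate 1. The immunoglobulin genes Ighm and Jchain stood at −1.25 (SE 0.31) and −1.39 (SE 0.36). Macrophage and Kupffer cell markers had a median of −0.27 over 18 genes and 0 past the threshold adjusted over the list alone (camera adjusted p = 0.00051; adjusted p = 0.67 with an estimated correlation), with the scavenger receptor Marco at −1.82 (SE 0.61). Acute phase genes had a median of −0.51 over 22 genes, 0 past the threshold adjusted over the list alone (camera adjusted p = 0.022; adjusted p = 0.92 with an estimated correlation). They scored 1.24 in WT FFD replicate 2 against −0.243 and −0.38 in the other WT FFD libraries. Without that library their median was 0.0285. Outside the called lists, 4 of 4 neutrophil markers were negative with a median of −0.76, and 6 of 6 blood cell genes with a median of −0.29 (0 past the threshold adjusted over the list alone, camera adjusted p = 0.052 for each; adjusted p = 0.67 with an estimated correlation for each). Neutrophil scores were 1.64 in WT FFD replicate 2, the library with raised acute phase genes, −0.0544 and 0.754 in the other WT FFD libraries and −0.21 to 0.32 in HKO FFD libraries.

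Drug metabolism genes were again mostly positive: 23 of 25 on FFD, with a median of 0.28 and 5 higher adjusted over the list alone (camera adjusted p = 3.8e-11; adjusted p = 0.14 with an estimated correlation). Cyp2b9 averaged 0.419 ± 0.285 CPM in WT and 5.69 ± 1.75 CPM in HKO mice, and Cyp2c37 360 ± 21.7 and 611 ± 16 CPM. Cyp2b9 is also among the 9 female-biased genes, of which 4 were higher and 2 lower adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.022; adjusted p = 0.24 with an estimated correlation). Of the 22 male-biased genes, 1 fell, Serpina1e, and 20 were negative, with a median of −0.30 and 3 lower adjusted over the list alone (camera adjusted p = 1.5e-07; adjusted p = 0.37 with an estimated correlation). Male-biased scores were −0.329 in WT FFD replicate 2, 0.554 and 0.296 in the other WT FFD libraries and −0.297 to −0.211 in HKO FFD libraries. PPARalpha targets had 7 higher adjusted over the list alone and a median of 0.057 over 23 (camera adjusted p = 4.9e-05; adjusted p = 0.37 with an estimated correlation). Among these, Pdk4, a kinase that restrains glucose oxidation, averaged 7.86 ± 0.864 CPM in WT and 27 ± 3.39 CPM in HKO mice. The gluconeogenesis list had a median of 0.34 over 14 genes and 2 higher adjusted over the list alone (camera adjusted p = 0.0053; adjusted p = 0.37 with an estimated correlation), with Igfbp1 at 1.5 (SE 0.33) and the phosphoenolpyruvate carboxykinase Pck1 at 0.47 (SE 0.15).

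A further 4 lists shifted on FFD with 0 members past the threshold adjusted over the list alone. Medians were −0.30 over 20 ER stress genes (camera adjusted p = 0.00051; adjusted p = 0.81 with an estimated correlation) and 0.12 over 23 NRF2 targets, the antioxidant genes (camera adjusted p = 0.025; adjusted p = 0.39 with an estimated correlation). ER stress scores were 0.0915 in WT FFD replicate 2, −0.279 and −0.413 in the other WT FFD libraries and −0.651 to −0.387 in HKO FFD libraries, and without that replicate the list's median was −0.187 and it no longer passed. Medians were −0.08 over 21 hepatocyte identity genes (camera adjusted p = 0.01; adjusted p = 0.37 with an estimated correlation) and 0.08 over 35 ribosomal protein genes (camera adjusted p = 0.022; adjusted p = 0.92 with an estimated correlation). Of the genes fixed in advance, log2 fold changes on FFD were 0.64 (SE 0.25) for Ppargc1a, −0.04 (SE 0.07) for Tfam, −0.17 (SE 0.12) for Fasn, −0.25 (SE 0.25) for Scd1 and −0.22 (SE 0.12) for Cpt1a. They were −0.29 (SE 0.59) for Cyp7a1, 0.02 (SE 0.73) for Fgf21, 0.77 (SE 0.58) for Col1a1, 1.10 (SE 0.49) for Trem2 and 0.16 (SE 0.12) for Alb, none past the threshold. The Serpina1e call ended without WT FFD replicate 1, HKO FFD replicate 2 or HKO FFD replicate 3 and with only the 2 groups compared (Benjamini-Hochberg adjusted p = 0.05, 0.19, 0.071 and 0.07 by edgeR's quasi-likelihood test, against 1.4e-15 to 0.19 over all alternatives), and 30 genes passed without HKO FFD replicate 1 and 5 without WT FFD replicate 3. The camera calls of the gluconeogenesis, NRF2, ER stress, acute phase, hepatocyte identity, female-biased and ribosomal lists ended with some library left out. The other 9 splits of the 6 FFD libraries called 6 to 11 lists against the 13 of the real one, too few splits for a share under 0.05.

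**Figure D2:**
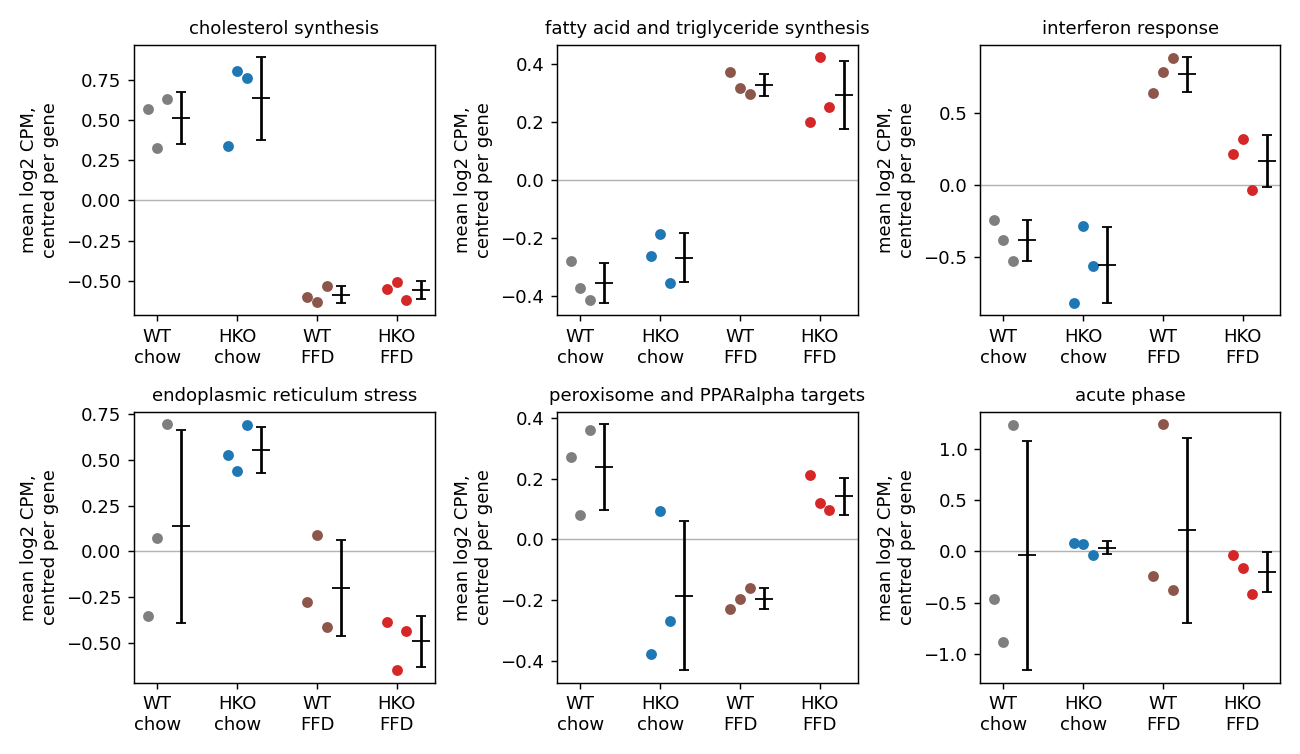
Scores of 6 gene lists in each library (mean log2 CPM of the list's genes, each centred on its mean over the 12 libraries), by group; points are libraries and the bars mean ± SD of 3. Cholesterol synthesis lies between 0.327 and 0.807 on chow and between −0.632 and −0.508 on FFD, and the acute phase panel shows WT chow replicate 3 and WT FFD replicate 2 at 1.23 and 1.24.

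The third comparison asks what the diet changed in WT livers, and here 1177 genes rose and 944 fell, 339 and 197 of them more than 2-fold. The stearoyl-CoA desaturase Scd1 rose 15.7-fold, from 1322 ± 475 to 20700 ± 3530 CPM, and the cholesterol synthesis enzymes Idi1 and Sqle fell 13.5-fold and 11.3-fold, from 16.3 ± 3.03 to 1.2 ± 0.142 and from 18.7 ± 9.43 to 1.64 ± 0.492 CPM (adjusted p = 2.8e-05, 0.00017 and 2e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The other large increases were the adipsin gene Cfd at a log2 fold change of 7.72 (SE 1.4), the lipid droplet protein gene Cidea at 5.74 (SE 0.94) and Themis at 4.74 (SE 0.53). Next came Cyp21a1 at 3.93 (SE 0.37), Clec2h at 3.86 (SE 0.65) and the transcription factor gene Onecut1 at 3.80 (SE 0.72). Lmod2 had 1 count in all WT chow libraries and 68 on FFD, a ratio of 61.1 with a 95% counting interval of 10.6 to 2450. Other large decreases included Nipal1 at −3.82 (SE 0.73), Slc34a2 at −3.12 (SE 0.63), Gadd45b at −2.91 (SE 0.67) and the asparagine synthetase Asns at −2.57 (SE 0.58). Slc35f1 had 100 counts on chow and 3 on FFD, a ratio of 37.1 with an interval of 12.3 to 183.

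Lipid genes moved in several directions in WT livers. In cholesterol synthesis and uptake 19 of 25 genes fell and 0 rose, with 20 lower and 2 higher adjusted over the list alone (camera adjusted p = 7.2e-21; adjusted p = 0.069 with an estimated correlation). Hsd17b7 fell by 1.26 and Cyp51 fell by 2.15 on the log2 scale. Of 22 genes of fatty acid and triglyceride synthesis 10 rose and 1 fell, with 11 higher and 3 lower adjusted over the list alone (camera adjusted p = 9.3e-06; adjusted p = 0.16 with an estimated correlation). Srebf1, which drives that pathway, rose by 2.51 (SE 0.23) and the desaturase Fads2 by 0.77 (SE 0.10). Of 24 lipid droplet and uptake genes 7 rose and 5 fell, with 10 higher and 5 lower adjusted over the list alone (camera adjusted p = 7e-04; adjusted p = 0.45 with an estimated correlation). The fatty acid transporter Cd36 rose by 1.82 (SE 0.20) and the perilipin Plin4 by 1.47 (SE 0.17), and the log2 fold change of Hsd17b13 was −0.66 (SE 0.11). Among 23 PPARalpha targets 6 fell and 2 rose, with 9 lower and 4 higher adjusted over the list alone (camera adjusted p = 0.0088; adjusted p = 0.58 with an estimated correlation). Cyp4a14, a fatty acid hydroxylase, went from 7281 to 1930 CPM, and the log2 fold change of Vnn1 was 0.92 (SE 0.20). Of 6 ketogenesis genes 2 fell, also adjusted over the list alone, among them Slc16a1 (camera adjusted p = 0.044; adjusted p = 0.58 with an estimated correlation). Of 23 genes of bile acid synthesis and transport 6 rose and 2 fell, with 7 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0092; adjusted p = 0.58 with an estimated correlation). The risers with the smallest p were Abcg5 and Abcg8, which form a sterol exporter and overlap each other on opposite strands, at 2.43 (SE 0.18) and 1.90 (SE 0.16).

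Immune genes were higher on FFD in WT livers. Of 29 interferon response genes 24 rose and 0 fell, with 27 higher adjusted over the list alone (camera adjusted p = 1.5e-29; adjusted p = 0.069 with an estimated correlation). The guanylate-binding protein gene Gbp7 rose by 1.93 (SE 0.16). Of 20 lymphocyte and dendritic cell markers 6 rose, 8 adjusted over the list alone (camera adjusted p = 0.00022; adjusted p = 0.58 with an estimated correlation), among them Ighm by 1.71 (SE 0.32) and Cd4 by 2.02 (SE 0.43). Of 18 macrophage and Kupffer cell markers 4 rose, 7 adjusted over the list alone (camera adjusted p = 0.0014; adjusted p = 0.58 with an estimated correlation), Cd5l by 0.65 (SE 0.16). Macrophage scores were −0.548 in WT chow replicate 1, 0.164 and 0.152 in the other WT chow libraries and 0.187 to 0.338 in WT FFD libraries, and without WT chow replicate 1 the list's median was 0.195 and it no longer passed. Of 14 markers of lipid-associated and recruited macrophages 6 rose, 6 also adjusted over the list alone (camera adjusted p = 0.022; adjusted p = 0.58 with an estimated correlation). Among these Gpnmb rose by 3.61 (SE 0.90), a call lost without WT chow replicate 2 or 3 or WT FFD replicate 3.

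Zonation, stress and translation genes also differed by diet in WT livers. Of 18 pericentral genes 7 rose and 0 fell, with 9 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00022; adjusted p = 0.12 with an estimated correlation). Slc13a3 rose by 2.04 (SE 0.19) and Lect2 by 1.29 (SE 0.16). Of 14 periportal genes 5 fell, 5 also adjusted over the list alone (camera adjusted p = 0.017; adjusted p = 0.58 with an estimated correlation), with Etnppl at −1.39 (SE 0.28). Of 19 genes of the integrated stress response 6 fell and 2 rose, with 8 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.004; adjusted p = 0.45 with an estimated correlation). The log2 fold change of its transcription factor Atf4 was −0.56 (SE 0.08) and that of the glutathione-degrading Chac1 2.46 (SE 0.49). Of 15 heat shock genes 7 fell, 9 adjusted over the list alone (camera adjusted p = 6.4e-05; adjusted p = 0.58 with an estimated correlation), with Hspa1b at −2.12 (SE 0.36). Heat shock scores were 0.825 in WT chow replicate 3 and 0.0143 and 0.575 in the other WT chow libraries. Of 35 ribosomal protein genes 22 fell, 28 adjusted over the list alone (camera adjusted p = 5.1e-10; adjusted p = 0.58 with an estimated correlation), with Rpl8 at −0.42 (SE 0.07). ER stress genes had 0 calls in WT and a median of −0.44 over 20 genes (0 adjusted over the list alone, camera adjusted p = 0.022; adjusted p = 0.81 with an estimated correlation). Their score was 0.696 in WT chow replicate 3 and −0.356 and 0.0733 in the other WT chow libraries. Without that replicate the ER stress median was −0.0828 and the list no longer passed. Of the 5 adipose genes 2 rose, 2 also adjusted over the list alone, Cfd and Car3 (camera adjusted p = 0.0077; adjusted p = 0.33 with an estimated correlation), and Car3 went from 241 to 1991 CPM.

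Of the genes fixed in advance other than Scd1, none passed in WT livers. Their log2 fold changes were −0.91 (SE 0.36) for Slc25a34 itself, −0.75 (SE 0.25) for Ppargc1a, −0.01 (SE 0.07) for Tfam, 0.04 (SE 0.12) for Fasn, 0.08 (SE 0.12) for Cpt1a and 1.46 (SE 0.60) for Cyp7a1. They were −2 (SE 0.70) for Fgf21, 0.38 (SE 0.61) for Col1a1, 0.36 (SE 0.54) for Trem2 and −0.30 (SE 0.12) for Alb. Column names number the FFD libraries 114 to 119 and the chow libraries 141 to 145 and 159, and if these numbers mark a preparation batch, it cannot be told apart from diet in either genotype. Within chow the numbers also ran by genotype, with HKO at 141 to 143 and WT at 144, 145 and 159. Within FFD, WT libraries were 114 to 116 and HKO libraries 117 to 119. A batch that split along these runs could not be told apart from genotype either. The camera calls of the ketogenesis, bile acid, periportal, ER stress and both macrophage lists ended with some library left out, the ketogenesis median being 0.0334 without WT chow replicate 3. Without the 2 libraries with raised acute phase genes 1187 genes passed instead of 2121, and 1113, 1409 and 1213 without WT chow replicate 2, WT FFD replicate 1 or WT FFD replicate 3.

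**Figure D3:**
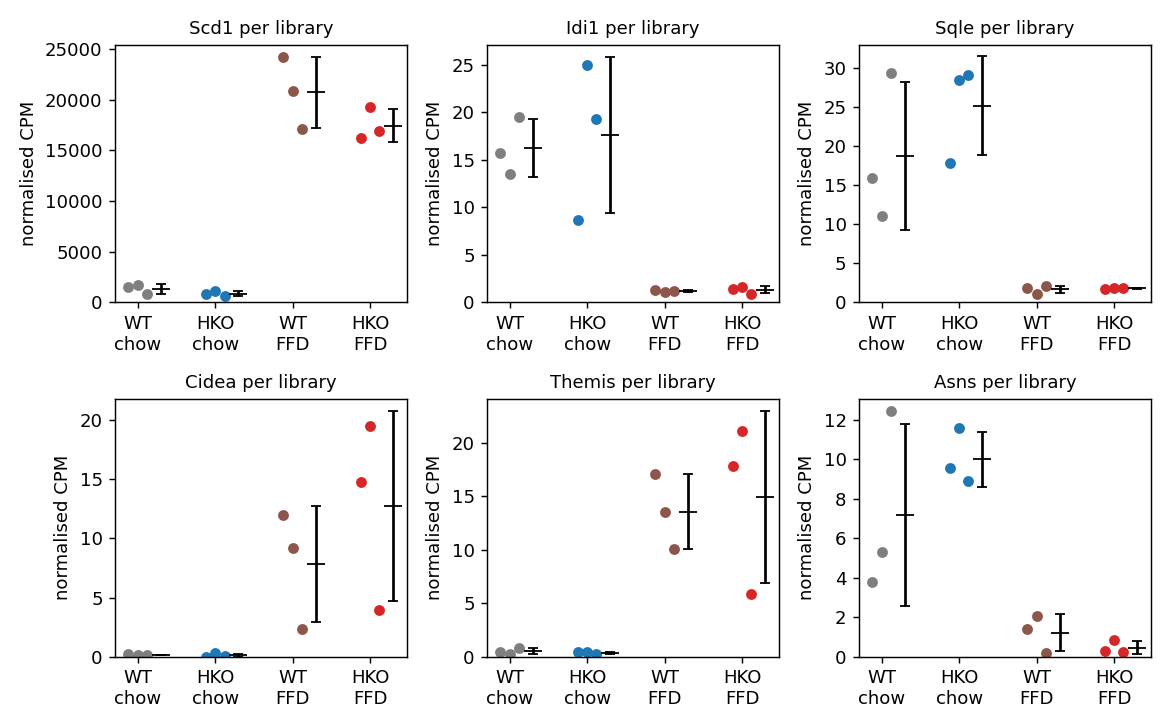
Normalised CPM of Scd1, Idi1, Sqle, Cidea, Themis and Asns in each library, by group; points are libraries and the bars mean ± SD of 3. Scd1 averaged 1322 and 846 CPM on chow and 20700 and 17420 CPM on FFD in WT and HKO mice, and Idi1 16.3 and 17.6 CPM on chow and 1.2 and 1.31 CPM on FFD.

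The fourth comparison asks the same of HKO livers, where 1065 genes rose and 874 fell, 283 and 196 of them more than 2-fold. Scd1 rose 20.6-fold, from 846 ± 225 to 17420 ± 1620 CPM, Sqle and Idi1 fell 14-fold and 13.9-fold, and the hormone gene Enho fell 11.9-fold, from 16.5 ± 4.14 to 1.37 ± 0.484 CPM (adjusted p = 1.3e-05, 0.00014, 0.00014 and 1.3e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Other large increases were Cidea at 6.55 (SE 0.94), Themis at 5.4 (SE 0.57), Cyp2a22 at 5.02 (SE 0.61), H2-Q1 at 4.73 (SE 0.57), Osbpl3 at 4.11 (SE 0.48), Nrep at 4.04 (SE 0.60) and Stap1 at 4.01 (SE 0.56). The other large decreases were Moxd1 at −5.14 (SE 1), Asns at −4.51 (SE 0.66), Pdlim3 at −4.30 (SE 1.1) and Cpe at −3.75 (SE 0.98). Slc35f1 had 55 counts on chow and 2 on FFD, a ratio of 33.3 with a 95% counting interval of 8.8 to 282. The Pdlim3 and Cpe calls ended without HKO chow replicate 2 or any of the HKO FFD libraries.

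Cholesterol synthesis had the same number of calls as in WT, 19 of 25 lower and 0 higher, with 20 lower and 1 higher adjusted over the list alone (camera adjusted p = 6.1e-25; adjusted p = 0.1 with an estimated correlation). Of 22 fatty acid and triglyceride synthesis genes 10 rose and 3 fell, with 11 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00057; adjusted p = 0.35 with an estimated correlation). The acyltransferase gene Mogat1 rose by 3.2 (SE 0.48). Of 24 lipid droplet and uptake genes 9 rose and 1 fell, with 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 8.2e-10; adjusted p = 0.11 with an estimated correlation). Plin4 rose by 2.59 (SE 0.18) and Cd36 by 2.55 (SE 0.20). Of 23 PPARalpha targets 9 rose and 2 fell, with 9 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0097; adjusted p = 0.68 with an estimated correlation). The thioesterase genes Acot3 and Acot4 rose by 2.15 (SE 0.34) and 1.05 (SE 0.16). Of 20 fatty acid oxidation genes 4 rose and 0 fell, with 5 higher adjusted over the list alone (camera adjusted p = 0.037; adjusted p = 0.84 with an estimated correlation), Hadh by 0.70 (SE 0.09) and Acadm by 0.46 (SE 0.09). Of 22 citric acid cycle genes 5 rose and 1 fell, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.04; adjusted p = 0.87 with an estimated correlation), Suclg2 rising by 0.71 (SE 0.10). In WT livers 5 of these 22 genes rose and 0 fell, 5 also adjusted over the list alone (camera adjusted p = 0.14, and 0.81 with an estimated correlation).

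ER stress genes fell in HKO livers, 15 of 20, with 17 lower adjusted over the list alone (camera adjusted p = 1.5e-14; adjusted p = 0.38 with an estimated correlation). The chaperone Hyou1 went from 434 ± 49.5 to 125 ± 20.9 CPM and Sdf2l1 from 58.9 ± 16.7 to 9.77 ± 1.98 CPM. Of 29 interferon response genes 14 rose and 0 fell, with 23 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.7e-11; adjusted p = 0.35 with an estimated correlation). Gbp7 rose by 1.35 (SE 0.16). Of 25 drug metabolism genes 9 rose and 2 fell, with 14 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0079; adjusted p = 0.57 with an estimated correlation), Cyp2b9 rising by 3.32 (SE 0.65). In WT livers 5 of these 25 genes rose and 3 fell, 5 and 4 adjusted over the list alone (camera adjusted p = 0.094, and 0.59 with an estimated correlation). Of 22 male-biased genes 8 fell, with 10 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00012; adjusted p = 0.57 with an estimated correlation), Serpina1e from 4769 ± 624 to 728 ± 243 CPM. Of 18 pericentral genes 6 rose, with 7 higher adjusted over the list alone (camera adjusted p = 0.034; adjusted p = 0.38 with an estimated correlation). Of 14 periportal genes 5 fell, with 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0019; adjusted p = 0.57 with an estimated correlation). Of 15 heat shock genes 4 fell, with 6 lower adjusted over the list alone (camera adjusted p = 0.0016; adjusted p = 0.78 with an estimated correlation). Of 35 ribosomal protein genes 25 fell, with 31 lower adjusted over the list alone (camera adjusted p = 1.5e-12; adjusted p = 0.53 with an estimated correlation). Of the 5 adipose genes 3 rose, with 3 higher adjusted over the list alone (camera adjusted p = 0.012; adjusted p = 0.38 with an estimated correlation). These were Cfd, Car3 and Cidec, and the Cfd and Cidec calls ended without HKO chow replicate 1 or 3 or HKO FFD replicate 1 or 2.

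Of the genes fixed in advance, Fasn fell in HKO livers by 0.54 (SE 0.12; adjusted p = 0.0095 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Log2 fold changes of the others, apart from Scd1, were −0.31 (SE 0.57) for Slc25a34, −0.39 (SE 0.24) for Ppargc1a, 0.08 (SE 0.07) for Tfam, 0.24 (SE 0.12) for Cpt1a and 0.67 (SE 0.59) for Cyp7a1. They were −0.08 (SE 0.73) for Fgf21, 0.47 (SE 0.58) for Col1a1, 1.18 (SE 0.51) for Trem2 and 0.01 (SE 0.12) for Alb, none past the threshold. Without HKO chow replicate 1 or 3, or HKO FFD replicate 1 or 2, 1261, 1064, 1144 and 967 genes passed instead of 1939. The camera calls of the fatty acid oxidation, citric acid cycle, drug metabolism, pericentral and adipose lists ended with some library left out. The other splits of the 6 libraries of either genotype called 0 genes, but up to 17 lists in WT and up to 19 in HKO mice, against 17 and 15 for the real ones. These splits mix chow and FFD libraries within each group, which widens the spread within groups. They therefore cannot rank the counts of single genes against the list tests.

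Diet effects were similar in both genotypes. Across the 14277 genes, which are not independent replicates, the log2 fold changes for diet in WT and in HKO mice had a Pearson r of 0.572 and a Spearman rho of 0.524. Genes higher on FFD in both genotypes numbered 634 where independent lists would share 87.8, and genes lower in both 381 against 57.8. Only 2 genes were called in opposite directions, and of the 3043 genes called in either genotype 92.3% had the same sign in both. The genotype effects on chow and on FFD had an r of 0.0799 and a rho of 0.0811, and shared 0 calls in either direction, against 0.00021 expected among genes lower in both. The edgeR test called 3 and 1 genes in all, with 1680 and 1333 at an unadjusted p under 0.05, and DESeq2 119 and 130.

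**Figure D4:**
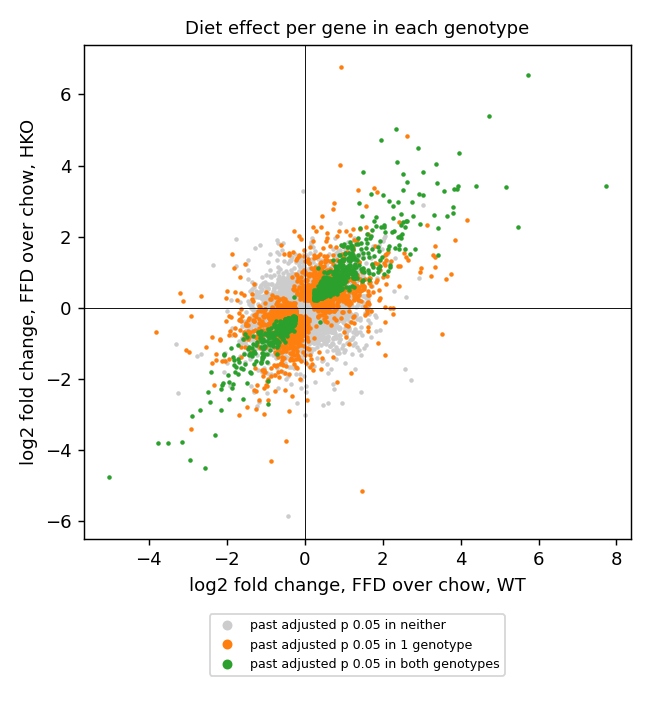
Log2 fold change of FFD over chow per gene in WT (horizontal axis) and HKO livers (vertical axis) for the 14277 tested genes, coloured by whether the gene passed an adjusted p of 0.05 in neither, 1 or both genotypes. Most genes called in both lie where both changes have the same sign, and the Pearson r is 0.572.

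The interaction asks whether the diet effect differed between genotypes. No gene passed edgeR's quasi-likelihood test (0 genes, against 1293 at an unadjusted p under 0.05 where chance gives 714 on average, and 87 by DESeq2). The smallest p belonged to Serpina1e at −1.76 (SE 0.27), the complement gene C4a at −1.94 (SE 0.34) and Odf3b at 0.85 (SE 0.15), all with an adjusted p of 0.23 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among PPARalpha targets all 23 interaction values were positive, with a median of 0.31 and 10 higher adjusted over the list alone (camera adjusted p = 1.2e-12; adjusted p = 0.33 with an estimated correlation), with Acot3 at 2.42 (SE 0.46) and Acot4 at 1.07 (SE 0.22). Fatty acid oxidation had 17 of 20 positive, a median of 0.14 and 2 higher adjusted over the list alone (camera adjusted p = 0.0026; adjusted p = 0.53 with an estimated correlation). Ketogenesis had 6 of 6 positive, a median of 0.24 and 1 higher adjusted over the list alone (camera adjusted p = 0.0088; adjusted p = 0.42 with an estimated correlation). Lipid droplet genes had 19 of 24 positive, a median of 0.18 and 2 higher adjusted over the list alone (camera adjusted p = 0.0031; adjusted p = 0.42 with an estimated correlation), with Plin4 at 1.12 (SE 0.24).

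Negative interaction values, a lower log2 fold change with diet in HKO than in WT livers, covered immune, ER stress and male-biased genes. Medians were −0.41 over 29 interferon genes with 1 lower adjusted over the list alone (camera adjusted p = 2.4e-07; adjusted p = 0.42 with an estimated correlation), and −0.93 over 20 lymphocyte markers with 3 lower adjusted over the list alone (camera adjusted p = 1.6e-07; adjusted p = 0.42 with an estimated correlation). They were −0.60 over 20 ER stress genes with 0 lower adjusted over the list alone (camera adjusted p = 1.8e-10; adjusted p = 0.42 with an estimated correlation). The median was −0.56 over 22 male-biased genes with 6 lower adjusted over the list alone (camera adjusted p = 1.4e-10; adjusted p = 0.41 with an estimated correlation), whose diet medians were 0.24 in WT and −0.36 in HKO livers. Complex I of the respiratory chain had a median of −0.10 over 37 genes with 0 lower adjusted over the list alone (camera adjusted p = 0.019; adjusted p = 0.89 with an estimated correlation). Of the genes fixed in advance, interaction values were 0.60 (SE 0.69) for Slc25a34, 0.36 (SE 0.35) for Ppargc1a, 0.09 (SE 0.10) for Tfam, −0.59 (SE 0.16) for Fasn, 0.39 (SE 0.36) for Scd1 and 0.16 (SE 0.17) for Cpt1a. They were −0.79 (SE 0.84) for Cyp7a1, 1.91 (SE 1) for Fgf21, 0.09 (SE 0.84) for Col1a1, 0.82 (SE 0.75) for Trem2 and 0.32 (SE 0.17) for Alb. The camera calls of the lipid droplet, ketogenesis and complex I lists ended with some library left out, and the PPARalpha median was 0.582 without WT FFD replicate 3 and 0.487 without HKO chow replicate 2. Of 99 other regroupings 76 called at least as many lists as the 9 found here, and 81 genes passed without HKO chow replicate 2.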

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

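The tests that regroup the libraries, the interaction test and camera at an estimated correlation were chosen before the results were seen, and the tests of the 3 patterns below after. The interaction test found 9 gene lists whose diet effect differed between HKO and WT livers by camera, and their median interaction values (log2) are the differences singled out here. They were 0.307 for peroxisome and PPARalpha targets, 0.241 for ketogenesis, 0.184 for lipid droplet proteins, 0.135 for mitochondrial fatty acid oxidation, −0.0993 for respiratory complex I, −0.6 for ER stress, −0.414 for the interferon response, −0.926 for lymphocyte markers and −0.556 for male-biased genes. With a correlation between genes estimated from the data none passed, with a smallest adjusted p of 0.33.

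Other groupings of the same libraries show how far chance can be excluded. For the interaction, 77 of 100 regroupings, the real one included, called at least the 9 lists found, with up to 22 in another, so chance cannot be excluded for the number of lists. The 0 genes called by edgeR there (1293 at an unadjusted p under 0.05, 87 by DESeq2) are a number that all 100 must reach, with up to 15 in another, so this test says nothing about chance. The agreement of the genotype effect between diets, r = 0.0799, was matched or passed in distance from 0 by 41 of 100, with up to 0.199 in another, so chance cannot be excluded. The agreement of the diet effect between genotypes, r = 0.572, was reached in distance from 0 by 1 of 100, the real one, the smallest share this test can give. The farthest other lay 0.465 from 0, at −0.465, so chance is unlikely. A preparation batch that followed the library numbers could give the same agreement. Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. The real split and the highest other called 3 and 3 genes for genotype on chow (2 of 10 as high), 1 and 1 on FFD (2 of 10), 2121 and 0 for diet in WT (1 of 10) and 1939 and 0 in HKO mice (1 of 10). For lists the numbers were 13 and 20 (6 of 10), 13 and 11 (1 of 10), 17 and 17 (2 of 10) and 15 and 19 (3 of 10).

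The first pattern weighed is the lower level of Tmem82, the gene next to Slc25a34, in HKO livers. If reads ran on from Slc25a34 into Tmem82, Tmem82 should lose at most about as many reads per kb of exon as Slc25a34. The ratio of the losses was 1.3 (SE 0.23) on chow and 0.932 (SE 0.32) on FFD, so run-on transcription cannot be told apart from a lower level of Tmem82 itself. Of the 5 other tested genes within 100 kb, 0 were lower by more than 2 SE in both diets. Their SE on chow ran from 0.08 for Spen to 0.37 for Fblim1, so smaller shifts could be missed. A wider effect of the deletion and an effect on Tmem82 alone both stay open. Biological regulation of Tmem82 by loss of the carrier was not tested.

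The second pattern is the lower interferon and lymphocyte values in HKO livers on FFD. The tables argue against 1 library setting the interferon difference, since the median nearest 0 with a library left out was −0.504 (SD 0.06), and against a lower share of all non-hepatocyte cells. Endothelial and stellate scores minus the list score were 0.983 (SE 0.35) higher in HKO than in WT livers for the lymphocyte list and 0.732 (SE 0.066) higher for the interferon list. These scores do not speak to a lower share of immune cells alone, which stays open. Macrophage and Kupffer cell scores on FFD were 0.338, 0.187 and 0.302 in WT and 0.129, −0.0479 and −0.152 in HKO livers. Open are 1 library setting the lymphocyte difference, whose median nearest 0 was −0.51 (SD 0.26) and farthest −1.26, and the vector's cargo, since Cre and green fluorescent protein cannot be told apart from genotype and the interferon difference on chow was −0.172 (SE 0.17). A response of the liver to loss of the carrier stays open, untested, and so does a lower content of blood, with medians of blood cell genes of −0.289 on FFD and −0.271 on chow. On chow, however, the lymphocyte list had a median of 0.22 with 15 of 20 positive, and the interferon list −0.168 with 20 of 29 negative. Blood cell scores on FFD also overlapped, at −0.272, 0.353 and 0.501 in WT and −0.0747, 0.368 and −0.518 in HKO livers.

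The third pattern is the PPARalpha target list in HKO against WT livers. Its median was −0.25 on chow, with 22 of 23 negative, and 0.057 on FFD, with 14 of 23 positive. By camera at an estimated correlation neither passed (adjusted p = 0.35 and 0.37). The 16 of 23 members outside the Acot and Cyp4a families had an interaction median of 0.257. Reads divided within these families cannot change the members outside them, whose interaction values were all positive. The interaction of their mean score, a different measure, had an SE of 0.2 between libraries, so a difference from 0 in these members stays open. How far shared reads set the Acot and Cyp4a values stays open as well. So does 1 library setting the difference, since the median with a library left out ran from 0.213 (SD 0.11), the nearest to 0, to 0.582 without WT FFD replicate 3, with 0.487 without HKO chow replicate 2. A shift in clock phase or fasting stage between the genotypes cannot be told apart from it either: a clock index differed by 1.08 (SE 0.27) between HKO and WT livers on FFD and by −0.549 (SE 0.32) on chow. An effect of the carrier on fatty acid use stays open, untested.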

How the results depend on the processing

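Leaving out together the 2 libraries with raised acute phase genes was chosen after the data were seen, and the other alternatives before. With size factors by relative log expression or the stricter filter, the number of genes called in each of the 5 comparisons stayed within 1.5 times the reported one, and no called list reversed with the former. On simulated counts of this depth and number of mice, drawn independently at the fitted spread, 25.4% to 38.8% of 1.5-fold changes were recovered. Outlying libraries and genes that vary together were not simulated, and what depth alone limits was not tested.

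For HKO against WT on chow, the 3 genes became 395 without a filter, 119 with DESeq2, 14 without the 2 libraries, 1 with only the 2 groups compared and 0 with the mouse number as a block. The range was 0 (without HKO replicate 1 or 3) to 313 (without HKO replicate 2). On FFD the 1 gene became 306 without a filter, 130 with DESeq2, 3 without the 2 libraries, 2 with the robust dispersion, 2 with the block, 2 with only the 2 groups compared, and 0 (without WT replicate 1, HKO replicate 2 or HKO replicate 3) to 30 (without HKO replicate 1). With only the 2 groups compared the FFD calls were Pdk4 and Cyp2c37, without Serpina1e, which stayed with the robust dispersion and the block. Without a filter 27184 genes gave a prior of 48.9 degrees of freedom instead of 4.6, and 379 and 304 of the calls were among the 14277 genes tested otherwise. For diet in WT, 2121 became 1187 without the 2 libraries and 1113 (without WT chow replicate 2) to 1925 (without WT chow replicate 1) leaving out 1 library; in HKO mice, 1939 became 967 (without HKO FFD replicate 2) to 1848 (without HKO chow replicate 2). The interaction count of 0 became 238 without a filter, 87 with DESeq2, 1 with the block and 0 to 81, the highest without HKO chow replicate 2. The cause was not tested for any of these changes.

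The numbers of called lists fell to 0 in all 5 comparisons with camera at an estimated correlation, whose model lets the genes of a list vary together. Fry's test for a shift in 1 direction called 0 on chow, 0 on FFD, 12 for diet in WT, 9 for diet in HKO mice and 0 for the interaction. Its mixed test, which takes changes in either direction together and gives no direction, called 15, 15, 35, 36 and 9 in that order. The block for the mouse number ended 2 of 13 list calls on chow and 0 of 13 on FFD. It ended 1 of 17 for diet in WT, 4 of 15 for diet in HKO mice and 0 of 9 for the interaction. Leaving out 1 library gave 8 to 16 lists for the interaction, the highest without HKO chow replicate 2. The agreement of the genotype effect was 0.117 with the stricter filter and −0.0282 (without WT chow replicate 3) to 0.0789. That of the diet effect was 0.632 with the stricter filter and 0.455 to 0.544. Slc25a34 on chow was −3.55 with the block (adjusted p = 0.052 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as for Tmem82 and Odf3b) and −3.76 to −3.24 leaving out 1 library. On FFD it passed with DESeq2 (−2.92, adjusted p = 7.5e-06 with Benjamini-Hochberg adjustment, beside edgeR's quasi-likelihood test) and was −3.69 to −2.52. Mouse numbers do not pair the samples: of 18 pairs 1 had r over 0.1, in a range of −0.11 to 0.12, and 3 of 12 libraries correlated best with their own number.

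The acute phase list on FFD reversed, with medians of 0.0285 without the 2 libraries and −0.725 to 0.0285 leaving out 1, the highest without WT FFD replicate 2. It was the only called list whose camera direction reversed. Camera's direction stayed for the heat shock proteins list, HKO vs WT on chow, and the ketogenesis list, FFD vs chow in WT, but their medians were 2.97e-05 and 0.0334 without WT chow replicate 3 and 0.00293 and 0.0141 without the 2 libraries. The other reversals were of genes not called. With the block, Fgf21 for diet in HKO mice was 0.00876. Ranges leaving out 1 library, for genotype on chow, were −0.363 to 1.05 for Col1a1, −0.0697 to 0.678 for Trem2, −1.12 to 0.184 for mt-Co3, −4.24 to 2.1 for Saa2, −0.313 to 4.35 for Cfd, −1.56 to 0.0309 for Car3 and −0.103 to 0.615 for Mylpf. On FFD they were −0.106 to 0.00563 for Tfam, −0.676 to 0.0667 for Cyp7a1, −0.181 to 0.245 for Fgf21, −0.713 to 0.034 for Hist1h1e and −0.627 to 0.384 for Mylpf. For diet in WT they were −0.0513 to 0.0609 for Tfam, −0.0135 to 0.108 for Fasn, −0.0101 to 0.157 for Cpt1a, −0.153 to 0.182 for Cela1 and −0.276 to 0.8 for Mylpf. In HKO mice they were −0.56 to 1.94 for Fgf21, −0.0226 to 1.51 for Col1a1, −0.0378 to 0.0758 for Alb, −0.126 to 0.71 for Tnnc1 and −0.486 to 0.191 for Mylpf. For the interaction they were −0.199 to 0.959 for Slc25a34, −0.411 to 1.13 for Col1a1, −0.959 to 0.117 for Mylpf and −0.0553 to 0.386 for Fabp2. The cause was not tested. Of 265 calls of named genes, 95 were lost leaving out some library, 41 of 262 with only the 2 groups compared, 33 with the block and 11 without a filter; 0 reversed.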

Other observations

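All values in this part come from the tests fixed beforehand, and no test was chosen after a result was seen. Mitochondrial carriers moved in both directions with diet. Of 38 mitochondrial carriers other than Slc25a34, 3 rose and 3 fell in WT livers and 4 rose and 2 fell in HKO livers. Adjusted over the list alone, 6 were higher and 4 lower in WT and 4 higher and 6 lower in HKO livers (camera adjusted p = 0.82 and 0.94; adjusted p = 0.95 with an estimated correlation in WT and 0.96 in HKO livers). The dicarboxylate carrier Slc25a10 rose in WT and in HKO livers by 0.65 (SE 0.12) and 0.66 (SE 0.12), the calcium-regulated carrier Slc25a23 by 0.52 (SE 0.09) and 0.47 (SE 0.09). The glutamate carrier Slc25a22 went from 455 to 264.7 CPM in WT livers, and Slc25a30 from 31.1 to 104 CPM in HKO livers. The fusion gene Mfn2 rose by 0.60 (SE 0.09) and 0.54 (SE 0.09). Of 29 genes of mitochondrial biogenesis, dynamics and mitophagy 1 rose in WT and 4 in HKO livers (1 and 4 higher adjusted over the list alone; camera adjusted p = 0.43 and 0.75; adjusted p = 0.81 with an estimated correlation in WT and 0.96 in HKO livers). Cytochrome c, Cycs, had log2 fold changes of −0.28 (SE 0.07) and −0.43 (SE 0.07). Of 13 mitochondrially encoded mRNAs 0 were called by edgeR or counted adjusted over the list alone in the comparisons of genotype and of diet (camera adjusted p = 0.16 to 0.74 for genotype, 0.71 and 0.94 for diet; adjusted p = 0.9 to 0.96 with an estimated correlation).

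Glucose and clock genes differed by diet without a shift of their lists by camera. The list of 17 glycolysis and glycogen genes had 2 higher and 2 lower in WT and 1 and 2 in HKO livers (the same counts adjusted over the list alone; camera adjusted p = 0.18 and 0.94; adjusted p = 0.55 with an estimated correlation in WT and 0.96 in HKO livers). Fry called that list higher in WT livers (adjusted p = 0.0043). Among 19 clock genes 5 rose and 4 fell in WT livers and 1 and 2 in HKO livers (7 and 4, and 3 and 3, adjusted over the list alone; camera adjusted p = 0.35 and 0.94; adjusted p = 0.58 with an estimated correlation in WT and 0.96 in HKO livers). Clock had −0.93 (SE 0.11) and −0.59 (SE 0.11). Camera tests for a shift in 1 direction, so it can miss a list whose members move both ways. Fry's mixed test gave the clock list an adjusted p of 9.7e-06 in WT and 9.2e-06 in HKO livers. That test called 35 and 36 of the 44 lists for diet, so it does not single out the clock. The urea cycle enzyme Asl went from 1156 to 557.3 CPM in WT and from 1325 to 636.5 CPM in HKO livers. Its list of 24 genes had 4 higher and 3 lower and 1 and 5 (4 and 3, and 2 and 5, adjusted over the list alone; camera adjusted p = 0.71 and 0.25; adjusted p = 0.95 with an estimated correlation in WT and 0.96 in HKO livers).

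Lists of further cell types, cell division, cell death and respiration did not shift with diet by camera. In WT and HKO livers in turn, 0 of 30 stellate cell and fibrosis genes rose and 1 fell in each, Mmp14 (1 and 1 lower adjusted over the list alone; camera adjusted p = 0.66 and 0.57; adjusted p = 0.95 with an estimated correlation in WT and 0.96 in HKO livers). Of 17 endothelial genes 1 and 0 rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.43 and 0.57; adjusted p = 0.83 with an estimated correlation in WT and 0.96 in HKO livers). Of 15 cholangiocyte and progenitor genes 2 rose and 2 fell in WT livers and 1 and 1 in HKO livers, and 2 and 2, and 2 and 1, adjusted over the list alone (camera adjusted p = 0.27 and 0.7; adjusted p = 0.81 with an estimated correlation in WT and 0.96 in HKO livers). Sox9 stood at −1.71 (SE 0.21) and −1.04 (SE 0.21) and Krt23 at 2.27 (SE 0.43) and 2.86 (SE 0.48). Of 4 neutrophil markers 1 and 0 rose, and of 17 chemokine, cytokine and receptor genes 2 rose and 1 fell in WT and 1 fell in HKO livers (camera adjusted p = 0.1 and 0.3, and 0.37 and 0.94; adjusted p = 0.58 with an estimated correlation for both lists in WT, 0.89 and 0.96 in HKO livers). Of 28 cell cycle genes 2 rose in WT and 1 rose and 1 fell in HKO livers, E2f8 by 0.99 (SE 0.28) and 1.75 (SE 0.29) (camera adjusted p = 0.43 and 0.57; adjusted p = 0.82 with an estimated correlation in WT and 0.96 in HKO livers). Of 21 p53 and cell death genes 4 rose and 2 fell, and 3 and 2, with the death receptor Fas at 0.51 (SE 0.13) and 0.59 (SE 0.13) (camera adjusted p = 0.82 and 0.94; adjusted p = 0.95 with an estimated correlation in WT and 0.96 in HKO livers). Of 8 histone genes 1 fell in WT and 1 rose in HKO livers (camera adjusted p = 0.43 and 0.75; adjusted p = 0.83 with an estimated correlation in WT and 0.96 in HKO livers). Of 39 genes of respiratory complexes II to V 1 rose and 1 fell, and 0 rose and 2 fell (camera adjusted p = 0.71 and 0.12; adjusted p = 0.95 with an estimated correlation in WT and 0.96 in HKO livers).

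Genes of tissues that can be dissected along with liver gave these values. Of 6 blood cell genes 1 rose and 1 fell in each genotype with diet, Alas2 by 0.66 (SE 0.15) in WT and 0.53 (SE 0.16) in HKO livers and Bpgm at −0.36 (SE 0.10) and −0.48 (SE 0.10) (camera adjusted p = 0.81 and 0.94; adjusted p = 0.95 with an estimated correlation in WT and 0.96 in HKO livers). Too few genes for a list test were expressed from pancreas (1), skeletal muscle (2) and gallbladder and gut (3). The pancreatic elastase Cela1 stood at 8.14 and 8.52 CPM in WT and at 9.59 and 5.27 CPM in HKO livers on chow and FFD. Fabp2 rose from 83.9 to 192.7 CPM in WT and from 61.3 to 167 CPM in HKO livers. Mylpf averaged between 0.594 and 0.826 CPM in the groups.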
